A study of Mus musculus with 12 samples.

How the data were processed

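Skin of C57BL/6 mice was irradiated with UVB at 0, 90, 180 or 360 mJ/cm2 with a phototherapy lamp, per the labels. It was flash frozen, RNA was extracted with Trizol, small RNA libraries were made with the NEBNext Multiplex kit and sequenced on an Illumina NextSeq, per the labels' protocols. Library preparation by ligation favours some RNA ends over others, so levels are best compared for one miRNA across libraries rather than between miRNAs. The submitters' processing notes name the genome build mm9; the aligner, the counter, the miRBase release, the adapter trimming and the interval between irradiation and sampling are not given in the sources used here.

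The values are CPM as deposited by the authors, 1519 mature miRNA arms in 12 libraries, and each library sums to 1e+06. In every library 100% of the values were whole multiples of 1 read, with a tolerance of 0.01 reads and a largest deviation of 1.9e-09, so reads were recovered as 3164422 to 8063815 per library. A count of 3 reads, the upper limit that a count of 0 allows, was worth 0.372 to 0.948 CPM. Reads are amplified without molecular identifiers, so such limits cover counting error only. No library was identical to another, and chi-square over degrees of freedom between replicates of a dose was 173 to 778, far from sampling noise. This argues against repeat sequencing of 1 library, and each was counted as 1 replicate. It does not tell separate animals from separate preparations of 1 sample. Of the 590 tested arms, 24 have values identical to another arm's in 11 sets, such as miR-199a-3p with miR-199b-3p and miR-467a-5p with miR-467b-5p; these, the miR-466, miR-467 and miR-669 arms, and miR-21b and miR-21c are uncertain because near-identical arms can share reads. Names are as the table gives them, without the species prefix.

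Groups were taken from the sample titles. The tests, the lists and most alternatives were chosen before the data were examined, on the assumption of a count table with edgeR as the test, and with a fallback for normalized values. Since the table held CPM, the planned edgeR test was run only as an alternative, on the recovered reads, and the reported test is the fallback. It is limma-trend (limma 3.58.1, R 4.3.3) on log2(CPM + 1), with a pseudocount of 1, on arms with at least 1 CPM in at least 3 libraries. The 12 libraries entered a single fit with a mean per group and no replicate term, so the 4 groups share an estimate of spread. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05, and are two-sided. The 6 comparisons of groups, the F test over all groups and a linear term in dose were fitted. An exact permutation test of 3 libraries against 3 cannot give a p under 0.1, so none is used for single miRNAs.

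A set of 21 lists was fixed from textbook knowledge: epithelial, miR-183/miR-96/miR-182 cluster, skeletal muscle, red blood cell, myeloid, shared leukocyte, inflammation-induced, wound or hyperproliferative epidermis, p53-responsive, hypoxia, endothelial, fibroblast and smooth muscle, miR-29 family, miR-17/miR-92 with related clusters, let-7 family, miR-15/16 family, miR-30 family, Dlk1-Dio3 locus, pigment cell, neural, and liver or gut. Members can belong to more than one list: 11 of 21 inflammation arms, 6 of 12 wound arms, 8 of 14 p53 arms and 2 of 6 myeloid arms are also in another. Skin itself expresses many of the marker arms, and no list is specific to a cell type. Each list was tested with camera at a preset correlation of 0.01 in the 3 comparisons with control, 63 tests adjusted together, with an estimated correlation and with fry as alternatives. fry tests whether the members move, on balance, in a direction, and does not compare them with other miRNAs.

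The miRNAs named follow a rule fixed beforehand. For each dose against control, these are the 10 largest folds up and the 10 largest down among those with adjusted p under 0.05 and a mean of at least 10 CPM, or the 5 smallest p in a direction where fewer than 5 pass. For dose against dose and for the trend they are 5 in each direction. Up to 4 per list with the smallest p at 360 mJ/cm2, the 10 most abundant, and miR-21a-5p, miR-31-5p, miR-34a-5p, miR-203-3p, miR-205-5p, miR-146a-5p, miR-155-5p, miR-223-3p, miR-210-3p, miR-132-3p, miR-1a-3p, miR-133a-3p and miR-451a are added. The rule gave 108 miRNAs, not all of which are mentioned. Other members of a list are named where a short count called for it, after their values were seen; these are miR-511-5p, miR-130b-5p, miR-21b, miR-21c, miR-1a-1-5p, miR-203b-3p, miR-29c-5p, miR-107-3p and let-7j, besides miR-136-5p and miR-200c-3p.

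For the comparisons that share the controls, 100 simulated sets of unchanged groups, controls included, were drawn with noise independent between miRNAs. The pipeline was tested on simulated data for 360 mJ/cm2 against control, with 200 miRNAs changed and 589 tested. The fit recovered 41 of 46 (89.1%) changed by -2 log2 units, 29 of 49 (59.2%) changed by -1, 15 of 49 (30.6%) changed by 1 and 46 of 50 (92%) changed by 2. There were 8 calls among unchanged miRNAs. The median estimate of the unchanged was -0.15, of those changed by 1 it was 0.62 and of those changed by -1 it was -0.98. Values are shares of a total, so a rise elsewhere lowers the rest. This may account for part of the asymmetry, which was not tested. After an initial run the simulated spread was revised and the 10 most abundant miRNAs were kept out of those changed, which did not remove this asymmetry. With no miRNA changed there was 1 call at 360 mJ/cm2, 2 in the F test, 1 in the trend and 0 lists. The simulated miRNAs were drawn independently, so the 0 lists cannot show how often camera calls lists of correlated members falsely. In the real data the estimated correlation was 0.74 in the epithelial, 0.61 in the miR-29 and 0.49 in the myeloid list.

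Alternatives chosen beforehand were DESeq2 size factors in place of the total, no filter or a mean of at least 10 CPM, limma without the trend, the groups compared alone, a replicate block, thresholds of 0.10 or of a fold of 1.5, pseudocounts of 0.1 and 10, each library left out, dose as a step number, and a single arm per name in lists. Alternatives added after the data were examined were edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, TMM factors, miR-21a-5p and miR-1a-3p left out of the totals, identical arms merged, UVB_90 replicate 3 with UVB_180 replicate 1 left out, and the test of hairpin neighbours without identical or near-identical arms and with 1 arm per hairpin. Hairpin neighbours came from a RefSeq table of assembly GRCm38.p6, of which no coordinate is printed because its build differs from mm9. GC content came from GENCODE hairpin sequences. It is that of the hairpin side holding the arm, cut at the midpoint, and not of the mature arm alone. Figures were drawn with matplotlib 3.10.9. Every library and every column of the table was used.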

Results

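Small RNA was sequenced from the skin of C57BL/6 mice, a common inbred strain, after ultraviolet B (UVB) irradiation, the band of ultraviolet light behind sunburn. The doses were 0 (control), 90, 180 and 360 mJ/cm2, with 3 libraries per dose and 12 in all. The design asked which microRNAs (miRNAs, short RNAs that repress mRNAs) differ between normal and acutely UV-damaged skin, and at which dose. The deposited table listed 1519 mature miRNA arms in CPM (reads of an arm per 1e+06 miRNA reads), of which 590 reached 1 CPM in at least 3 libraries and were tested. The control libraries held 8063815, 6044080 and 3764459 miRNA reads and those of 90 mJ/cm2 3383485, 4641395 and 4871528. Those of 180 mJ/cm2 held 3465518, 4769554 and 5060781 and those of 360 mJ/cm2 4059152, 3843933 and 3164422. A single read was worth 0.124 to 0.316 CPM. Fold changes are on the log2(CPM + 1) scale, which understates the change of scarce miRNAs, and the 95% interval of a log2 fold change reached 0.63 to either side at the median. The labels do not say whether the libraries of a dose came from separate animals, so p-values measure only the spread between these samples, which may be technical.

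The irradiated libraries were separated from the controls along the axis of greatest variance, which carried 50.2% of it. Controls lay between -16.15 and -12.55 on this axis and the UVB_360 libraries between 8.85 and 12.94. UVB_90 replicates 1 and 2 lay at -3.52 and -0.91, while UVB_90 replicate 3 lay at 7.31, beyond the UVB_180 libraries (0.61 to 4.52). UVB_90 replicate 3 and UVB_180 replicate 1 were each other's nearest library (Pearson r = 0.99 across miRNAs, which are not independent replicates). The nearest library of control replicate 3 was UVB_90 replicate 1 (r = 0.985), against a mean r of 0.982 with the other controls. miR-21a-5p took 2.01% to 2.69% of the reads in controls and 17.8% to 19.3% in UVB_360 libraries. miR-1a-3p, a muscle miRNA and the most abundant on average over the 12 libraries, took 7.79% of the reads in UVB_180 replicate 3 and 14.5% to 21.4% in the other libraries.

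**Figure D1:**
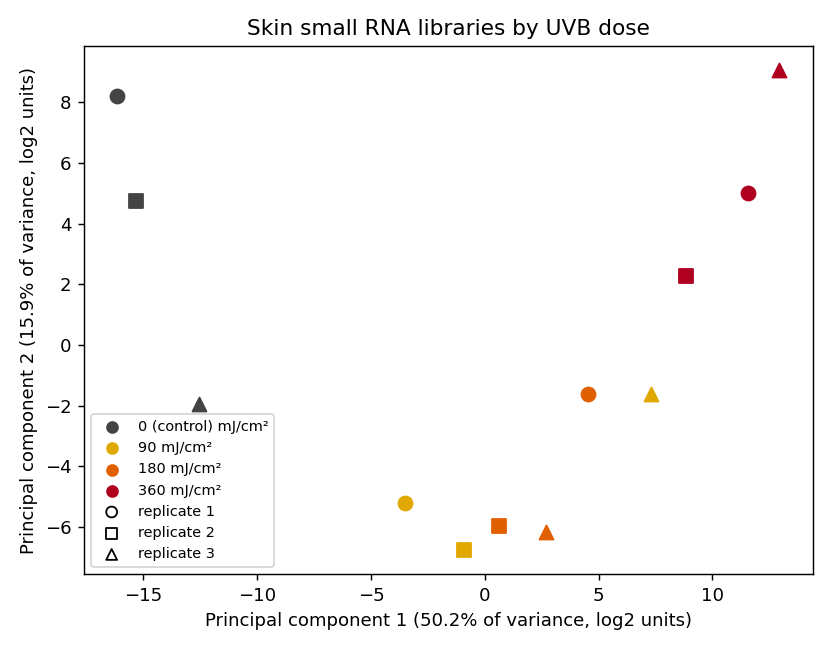
Principal components of the 590 tested miRNAs in 12 skin libraries, in log2 units; colours are UVB doses and symbols are replicates 1 to 3. Controls lie between -16.15 and -12.55 on component 1 (50.2% of the variance) and the 360 mJ/cm2 libraries between 8.85 and 12.94, with replicate 3 of 90 mJ/cm2 at 7.31.

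At 90 mJ/cm2, miR-21a-5p, which is induced in wounded and inflamed tissue, rose from 22599 ± 3726 CPM in controls to 107526 ± 36330 CPM (mean ± SD, n = 3 each). Its log2 fold change was 2.21 ± 0.25 (SE; limma adjusted p = 8.2e-05). All 4 arms of miR-34b and miR-34c, neighbouring hairpins under p53 control, rose by 1.75 to 2.48 log2 units, and miR-34b-5p went from 42.1 ± 16.5 to 227 ± 25.6 CPM (adjusted p = 8.2e-05). miR-34a-5p, which p53 also induces, did not pass, at -0.40 ± 0.22 (adjusted p = 0.20). miR-335-3p (2.77 ± 0.41) and miR-335-5p (1.79 ± 0.27), arms of a hairpin in the imprinted gene Mest, rose, as did miR-132-5p (1.85 ± 0.27), miR-132-3p (1.23 ± 0.29) and miR-212-5p (2.24 ± 0.34), products of neighbouring CREB-regulated hairpins. miR-375-3p fell by 2.65 ± 0.59 log2 units, miR-193b-3p by 2.29 ± 0.39, miR-200a-3p, an epithelial miRNA, by 2.19 ± 0.45 and miR-29c-3p, of a family that targets collagen mRNAs, by 2.11 ± 0.42. For each of the miRNAs that rose or fell here, all 3 irradiated libraries lay beyond all 3 controls. In total 78 miRNAs rose and 73 fell, 151 of the 590, and 222 (37.6%, where chance gives 10%) had no overlap between UVB_90 and control libraries. The share of calls that were up was 51.7%, 42.7% with TMM scaling factors and 59.9% with miR-21a-5p and miR-1a-3p left out of the totals.

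Of 14 arms of miRNAs typical of keratinocytes and other epithelia, 6 fell at 90 mJ/cm2, none rose and 8 did not pass, and adjusted over the list alone 7 fell. The list's median was -0.86 (limma's camera adjusted p = 0.0032, and adjusted p = 0.66 with an estimated correlation). Its level relative to the control mean was -1.86 log2 units in UVB_90 replicate 3, against -0.51 in each of the other replicates, and without replicate 3 the median was -0.41 (adjusted p = 0.030). Among 21 arms induced by NF-kB or cytokine signalling, 10 rose and none fell, 12 when adjusted over the list alone. Their median was 0.78 (camera adjusted p = 1.9e-05, and adjusted p = 0.50 with an estimated correlation). All 5 arms of the miR-29 family fell, 5 also adjusted over the list alone, with a median of -1.28 (adjusted p = 0.0045, and adjusted p = 0.50 with an estimated correlation). The list's level was 0.67, 0.12 and -0.79 in control replicates 1, 2 and 3, against -1.61, -1.47 and -1.01 in the UVB_90 libraries. Of 6 myeloid arms, miR-223-5p, miR-147-5p and miR-511-5p rose, and 4 rose adjusted over the list alone. Their median was 1.36 (adjusted p = 0.025, and adjusted p = 0.55 with an estimated correlation), and the list's level was 2.27 in UVB_90 replicate 3, against 0.55 and 0.83. Of 12 arms known from wounded or hyperproliferative epidermis, 5 rose and none fell, 5 also adjusted over the list alone. They were miR-21a-5p, both arms of miR-132, miR-130b-5p and miR-31-5p, and the list's median was 0.66 (adjusted p = 0.038, and adjusted p = 0.50 with an estimated correlation). Of 79 arms of the imprinted Dlk1-Dio3 locus, 13 rose and 6 fell, 11 and 4 adjusted over the list alone, with a median of 0.30 (adjusted p = 0.038, and adjusted p = 0.68 with an estimated correlation). Of these members, miR-147-5p did not pass without any control, UVB_90 replicate 3, UVB_180 replicate 1 or 3, or any UVB_360 library (adjusted p up to 0.21), and miR-511-5p without control replicate 1 or UVB_90 replicate 3 (up to 0.080). miR-31-5p did not pass without control replicate 1 or 2, UVB_90 replicate 1 or 2, UVB_180 replicate 2 or UVB_360 replicate 3 (up to 0.16), and miR-130b-5p without control replicate 1 (0.057). In the miR-29 family, miR-29b-3p did not pass without control replicate 1 (0.067), miR-29a-5p without control replicate 1 or 2 or UVB_90 replicate 2 (up to 0.10), miR-29a-3p without control replicate 1 or 2 or UVB_90 replicate 1 or 2 (up to 0.17), and miR-29c-5p without control replicate 1 or UVB_90 replicate 1 or 2 (up to 0.10). The myeloid call ended without control replicate 3 (adjusted p = 0.071) or UVB_90 replicate 3 (0.070, median 0.75), and the wound call without control replicate 3 (0.069) or UVB_90 replicate 1 (0.087). The Dlk1-Dio3 call ended without control replicate 3 (0.21) or UVB_90 replicate 3 (0.25). The 151 calls became 50 without control replicate 1, 96 without control replicate 2, 84 without UVB_90 replicate 3, and 71 without UVB_90 replicate 3 and UVB_180 replicate 1.

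At 180 mJ/cm2, miR-21a-5p reached 136828 ± 27726 CPM (n = 3), a log2 fold change of 2.59 ± 0.25 (limma adjusted p = 1.1e-05). The arms of miR-34b and miR-34c rose by 2.53 to 2.58, miR-335-3p by 2.71 ± 0.41, miR-129-5p, a miRNA best known from neurons, by 2.31 ± 0.35, and miR-223-5p by 2.13 ± 0.37. miR-31-5p, which rises in wounded and psoriatic epidermis, went from 256 ± 51.8 to 583 ± 135 CPM (1.18 ± 0.28, adjusted p = 0.0074). miR-211-5p, which lies in the melanocyte gene Trpm1, fell from 83.7 ± 31.8 to 19.5 ± 12.3 CPM (-2.19 ± 0.55, adjusted p = 0.0093). miR-375-3p fell by 2.64 ± 0.59 log2 units, miR-200a-3p by 2.12 ± 0.45 and miR-204-5p, a close relative of miR-211-5p, by 1.94 ± 0.29. In total 98 miRNAs rose and 83 fell (181 calls, 54.1% of them up, 41.2% up with TMM scaling factors and 63% up with miR-21a-5p and miR-1a-3p out of the totals), and 251 (42.5%, chance 10%) had no overlap with controls.

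The inflammation list rose again at 180 mJ/cm2, with 11 of 21 arms up and none down, 11 also adjusted over the list alone, and a median of 0.84 (camera adjusted p = 0.00013, and adjusted p = 0.50 with an estimated correlation). In the wound list, 7 of 12 arms rose and none fell, 7 also adjusted over the list alone, with a median of 1.11 (adjusted p = 0.0088, and adjusted p = 0.50 with an estimated correlation). miR-29 family arms fell in 4 of 5 cases (miR-29a-3p, miR-29a-5p, miR-29b-3p and miR-29c-3p), 5 adjusted over the list alone, with a median of -1.16 (adjusted p = 0.012, and adjusted p = 0.50 with an estimated correlation), or -0.77 without control replicate 1. Of 7 skeletal muscle arms, miR-133a-3p, miR-133b-3p and miR-1a-1-5p fell, 6 fell adjusted over the list alone, and the median was -0.84 (adjusted p = 0.016, and adjusted p = 0.50 with an estimated correlation). UVB_180 replicate 3, the library poor in miR-1a-3p, had a muscle level of -1.47 against -0.80 and -0.60 in replicates 1 and 2, and control replicate 3 had -0.56 against 0.30 and 0.26 in the other controls. Both miR-204-5p and miR-211-5p of the 3 pigment-cell arms fell, 2 also adjusted over the list alone, with a median of -1.94 (adjusted p = 0.024, and adjusted p = 0.50 with an estimated correlation). In the epithelial list miR-200a-3p, miR-141-3p, miR-429-3p and miR-203b-3p fell and 10 arms did not pass, 3 fell adjusted over the list alone, and the median was -0.46 (adjusted p = 0.025, and adjusted p = 0.68 with an estimated correlation). UVB_180 replicate 1 had an epithelial level of -1.17 against -0.50 and -0.48, and a myeloid level of 1.65 against 0.75 and 1.63. Of the 6 myeloid arms 4 rose, both arms of miR-147 with miR-223-5p and miR-511-5p, 4 also adjusted over the list alone, with a median of 1.46 (adjusted p = 0.027, and adjusted p = 0.55 with an estimated correlation). The let-7 list, 22 arms, had 6 down and none up, 5 down adjusted over the list alone, and a median of -0.26 (adjusted p = 0.045, and adjusted p = 0.56 with an estimated correlation). The Dlk1-Dio3 list had 21 up and 6 down, 23 and 6 adjusted over the list alone, and a median of 0.41 (adjusted p = 0.046, and adjusted p = 0.68 with an estimated correlation). Both arms of miR-147 did not pass without control replicate 1 or 2 or UVB_180 replicate 1 or 3 (adjusted p up to 0.15 and 0.082), nor miR-29a-5p without any of these (up to 0.11), and miR-29b-3p without control replicate 1 or UVB_180 replicate 3 (up to 0.088). miR-29a-3p did not pass without control replicate 1 or 2, UVB_90 replicate 1 or 2, any UVB_180 library or UVB_360 replicate 1 or 2 (up to 0.20). miR-133a-3p and miR-1a-1-5p did not pass without control replicate 1 or 2 or UVB_180 replicate 3 (up to 0.072 each), and miR-133b-3p without UVB_180 replicate 3 (0.052). miR-203b-3p did not pass without control replicate 1 or 2, UVB_90 replicate 1, UVB_180 replicate 1 or 2 or UVB_360 replicate 1 or 2 (up to 0.20). Leaving out control replicate 3 ended the calls of the epithelial (adjusted p = 0.10), myeloid (0.071), pigment-cell (0.10), let-7 (0.29, median -0.10) and Dlk1-Dio3 (0.22) lists. Leaving out UVB_180 replicate 1 ended those of the epithelial (0.11), myeloid (0.061) and Dlk1-Dio3 (0.061) lists, replicate 2 those of let-7 (0.081) and Dlk1-Dio3 (0.12), and replicate 3 that of muscle (0.055). UVB_90 replicate 3 (0.056 each) and UVB_360 replicate 2 (0.052 each) did so for let-7 and Dlk1-Dio3, and UVB_90 replicate 2 for Dlk1-Dio3 (0.051). The 181 calls became 90 without control replicate 1 and 106 without UVB_180 replicate 3.

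At 360 mJ/cm2, miR-223-3p, the miRNA typical of neutrophils and other myeloid cells, rose from 81.3 ± 22.8 to 1448 ± 268 CPM (n = 3 each), a log2 fold change of 4.16 ± 0.59 (limma adjusted p = 6.7e-05). miR-147-3p, which macrophages induce on Toll-like receptor stimulation, rose by 4.66 ± 0.57 from 1.73 ± 1.97 CPM, miR-139-5p by 2.65 ± 0.44, miR-142a-3p, a miRNA of blood cells, by 2.49 ± 0.34 and miR-155-5p, of activated leukocytes, by 1.24 ± 0.25. miR-21a-5p reached 183007 ± 8370 CPM (3.03 ± 0.25, adjusted p = 1.2e-06), and the arms of miR-34b and miR-34c rose by 2.62 to 2.83. miR-203-3p, which promotes keratinocyte differentiation, fell from 67050 ± 5483 to 15276 ± 11094 CPM (-2.36 ± 0.48, adjusted p = 0.0012) and miR-200a-3p from 3341 ± 582 to 180 ± 118 CPM (-4.38 ± 0.45, adjusted p = 7.1e-06). miR-375-3p (-3.97 ± 0.59), miR-211-5p (-3.93 ± 0.55), miR-193b-3p (-2.99 ± 0.39), miR-181c-5p (-2.75 ± 0.26) and miR-205-5p (-1.94 ± 0.38) also fell. miR-34a-5p fell by 0.92 ± 0.22 (adjusted p = 0.0037), against the direction of miR-34b and miR-34c. miR-31-5p had a log2 fold change of -0.15 ± 0.28, and miR-1a-3p, miR-148a-3p, miR-146a-5p, miR-210-3p and miR-451a also did not pass at this dose (adjusted p = 0.49 to 0.89). In total 119 miRNAs rose and 116 fell, 235 of the 590, and 291 (49.3%, chance 10%) had no overlap with controls. The share of calls that were up was 50.6%, 40.6% with TMM factors and 65.3% with miR-21a-5p and miR-1a-3p left out of each library's total.

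In the epithelial list at 360 mJ/cm2, 12 of 14 arms fell and none rose, 12 also adjusted over the list alone, with a median of -1.90 (camera adjusted p = 1.9e-05, and adjusted p = 0.50 with an estimated correlation). Of the 6 myeloid arms both arms of miR-223 and of miR-147 rose, 5 rose adjusted over the list alone, and the median was 3.68 (adjusted p = 0.0032, and adjusted p = 0.50 with an estimated correlation). In the inflammation list 12 of 21 arms rose and none fell, 13 rose and 2 fell adjusted over the list alone, and the median was 1.24 (adjusted p = 0.00014, and adjusted p = 0.50 with an estimated correlation). Those that rose included miR-21b (1.36 ± 0.25) and miR-21c (1.72 ± 0.26), whose sequences nearly match miR-21a-5p and which may share its reads. Of the miR-183/miR-96/miR-182 cluster, expressed in sensory and epithelial cells, miR-96-5p, miR-182-5p, miR-183-5p and miR-183-3p fell, 4 of 6 arms and 4 also adjusted over the list alone, with a median of -1.47 (adjusted p = 0.023, and adjusted p = 0.50 with an estimated correlation). All 3 pigment-cell arms fell, 3 also adjusted over the list alone, with a median of -2.70 (adjusted p = 0.017, and adjusted p = 0.50 with an estimated correlation). The miR-30 family had 7 of 11 arms down, 7 also adjusted over the list alone, and a median of -0.82 (adjusted p = 0.0068, and adjusted p = 0.50 with an estimated correlation). The let-7 list had 8 of 22 arms down and 1, let-7j, up, 8 and 1 also adjusted over the list alone, and a median of -0.50 (adjusted p = 0.016, and adjusted p = 0.50 with an estimated correlation); let-7b-5p fell by 1.87 ± 0.20. The Dlk1-Dio3 list had 20 arms up and 6 down, 17 and 6 adjusted over the list alone, and a median of 0.30 (adjusted p = 0.027, and adjusted p = 0.68 with an estimated correlation). miR-183-3p did not pass without control replicate 2 or UVB_360 replicate 1 or 3 (adjusted p up to 0.12), nor the pigment-cell arm miR-211-3p without control replicate 2 or 3 or any UVB_360 library (up to 0.15). Without control replicate 3 the calls of miR-183/miR-96/miR-182 (adjusted p = 0.075), pigment-cell (0.069), let-7 (0.089) and Dlk1-Dio3 (0.11) ended, and that of Dlk1-Dio3 also without UVB_360 replicate 2 (0.072, median 0.17).

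**Figure D2:**
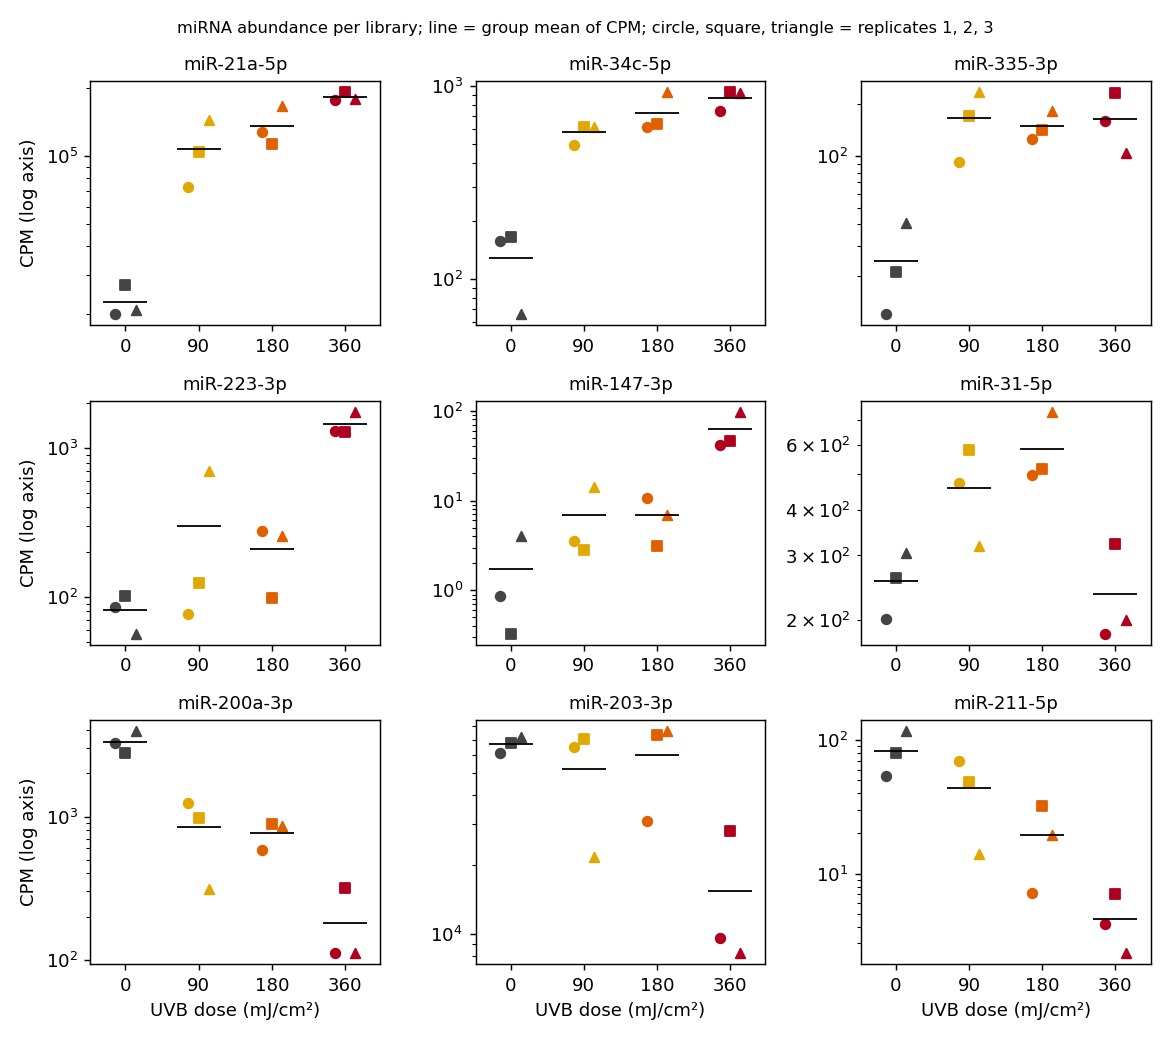
CPM on log axes of 9 miRNAs against UVB dose in mJ/cm2; each symbol is a library (circle, square and triangle for replicates 1, 2 and 3) and each line is the mean of 3 libraries. Mean miR-21a-5p was 22599 CPM in controls and 183007 CPM at 360 mJ/cm2, and mean miR-200a-3p was 3341 and 180 CPM.

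**Figure D3:**
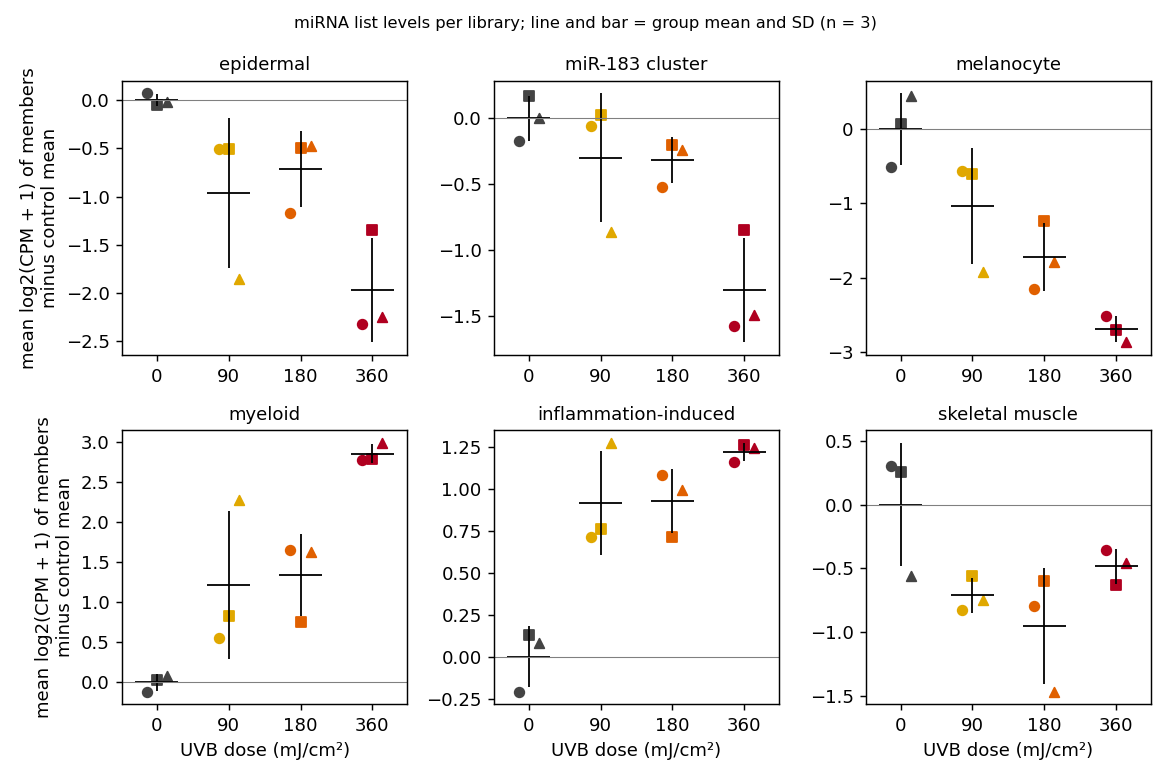
Level of 6 miRNA lists against UVB dose in mJ/cm2, as the mean log2(CPM + 1) of a list's members minus the control mean; symbols are libraries (circle, square and triangle for replicates 1, 2 and 3), and lines and bars are the mean and SD of 3 libraries. The epithelial list lay at -1.86 in replicate 3 of 90 mJ/cm2 and at -2.32, -1.35 and -2.25 at 360 mJ/cm2.

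The remaining lists had no camera call at any dose. The list known as p53-responsive (14 arms) had 5 up and 4 down at 360 mJ/cm2, 6 and 4 adjusted over the list alone, because only the miR-34b and miR-34c arms and miR-194-2-3p rose while miR-34a-5p, miR-107-3p, miR-143-3p and miR-145a-5p fell. miR-194-2-3p did not pass without control replicate 3 or UVB_360 replicate 2 (adjusted p up to 0.070), nor miR-143-3p without control replicate 1 or 2 or any UVB_360 library (up to 0.17). The p53 list's medians were -0.11, 0.16 and 0.35 at 90, 180 and 360 mJ/cm2 (camera adjusted p = 0.21, 0.38 and 0.19), and at 90 mJ/cm2 its mean was 0.49 and its test pointed up while its median was negative. fry, which does not compare members with other miRNAs, called it up at each dose (adjusted p = 0.015, 0.012 and 0.0047). Fibroblast and smooth muscle arms (15) had medians of 0.08, 0.37 and 0.53 (adjusted p = 0.46, 0.46 and 0.19), with miR-214-5p up by 1.46 ± 0.28 and miR-145a-5p down by 1.26 ± 0.22 at the highest dose. Of the 2 endothelial arms, miR-126a-3p rose to 1.47 ± 0.19 at 360 mJ/cm2 while miR-126a-5p was at 0.36 ± 0.24, and the list's adjusted p was 0.33, 0.21 and 0.18. The shared leukocyte list (12 arms) had medians of 0.26, 0.20 and -0.24 (adjusted p = 0.46, 0.78 and 0.75), and at 360 mJ/cm2 its mean was 0.25 and its test pointed up. Red blood cell arms (7) had medians of -0.13, 0.03 and 0.18 (adjusted p = 0.82, 0.95 and 0.65), hypoxia arms (2) 0.22, 0.89 and 0.42 (0.70, 0.19 and 0.61) and neural arms (12) 0.40, 0.36 and 0.10 (0.18, 0.19 and 0.82). Liver and gut arms (5) had medians of -0.25, 0.19 and 0.34 (adjusted p = 0.95, 0.94 and 0.32), with a mean of 0.10 and a test pointing up at 90 mJ/cm2. The miR-17/miR-92, miR-106a/miR-363 and miR-106b/miR-25 clusters (19 arms) had medians of -0.40, -0.34 and -0.23 (adjusted p = 0.070, 0.070 and 0.12), and the miR-15/16 family (14 arms) -0.15, -0.19 and 0.04 (0.69, 0.68 and 0.52), where miR-503-5p rose by 2.51 ± 0.28 and miR-497a-5p fell by 1.19 ± 0.21 at 360 mJ/cm2. Of the lists called at another dose, no call was made for muscle at 90 and 360 mJ/cm2 (medians -0.71 and -0.67, adjusted p = 0.071 and 0.29), wound at 360 mJ/cm2 (0.63, adjusted p = 0.073), miR-29 at 360 mJ/cm2 (-0.71, 0.14). Nor was a call made for miR-183/miR-96/miR-182 at 90 and 180 mJ/cm2 (-0.40 and -0.32, 0.46 and 0.39), miR-30 (-0.30 and -0.32, 0.082 and 0.060), let-7 at 90 mJ/cm2 (-0.14, 0.33) and pigment cells at 90 mJ/cm2 (-1.11, 0.10). None of the 23 list calls held with an estimated correlation.

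Much of the response was shared between doses, with 50 miRNAs up and 46 down at all 3. The 90 and 180 mJ/cm2 lists shared 64 miRNAs that rose and 60 that fell, where independent lists would share 13 and 10.3. Simulated unchanged groups, compared with simulated controls that they share, had 0.01 such miRNAs in common on average. The simulated noise was independent between miRNAs, so it lacks any shift that many miRNAs share in the real controls. The 90 and 360 mJ/cm2 lists shared 58 and 52 (independent 15.7 and 14.4, simulated 0), and the 180 and 360 mJ/cm2 lists 70 and 68 (independent 19.8 and 16.3, simulated 0). Fold changes correlated across miRNAs at r = 0.91, 0.82 and 0.84 for these pairs (simulated 0.50 each), and their covariance was 0.56, 0.66 and 0.728 (simulated 0.05 each, a difference of 0.509, 0.61 and 0.678). A single miRNA was called in opposite directions, miR-136-5p, at -0.94 ± 0.29 (adjusted p = 0.029) for 90 mJ/cm2 and 0.79 ± 0.29 (adjusted p = 0.041) for 360 mJ/cm2; it was named after its values were seen. It did not pass at 90 mJ/cm2 without control replicate 1 or UVB_90 replicate 1 or 2, or at 360 mJ/cm2 without control replicate 2 or 3, UVB_90 replicate 1, UVB_180 replicate 3 or UVB_360 replicate 1 or 3 (adjusted p up to 0.15 at each). The 3 controls cannot be split into parts of at least 2 libraries, so part of the excess may come from the shared controls.

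At 360 mJ/cm2, compared with 90 mJ/cm2, miR-147-3p was higher by 3.19 ± 0.57 log2 units (limma adjusted p = 0.0092), miR-223-3p by 2.92 ± 0.59 (adjusted p = 0.011) and miR-139-5p by 1.98 ± 0.44 (adjusted p = 0.015). miR-211-5p was at -2.83 ± 0.55 and miR-200a-3p at -2.18 ± 0.45 (adjusted p = 0.011 each), and miR-203-3p at -1.83 ± 0.48 (adjusted p = 0.027). miR-21a-5p was higher by 0.82 ± 0.25 (adjusted p = 0.043), while miR-31-5p was lower, at -0.96 ± 0.28 (adjusted p = 0.037). The myeloid miR-511-5p did not pass, at -0.42 ± 0.30 (adjusted p = 0.39), and the lists were tested only against control. Of the 590, 35 were higher and 31 lower, 66 calls (53% up, 44% up with TMM factors or 71.4% up with miR-21a-5p and miR-1a-3p out of the totals). The 66 calls became 0 without UVB_90 replicate 1 or without UVB_90 replicate 2, 18 without UVB_360 replicate 1 and 1 without UVB_360 replicate 3, and 88 without UVB_90 replicate 3. None of the 38 named calls held without each of the 12 libraries.

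Against 180 mJ/cm2, 360 mJ/cm2 gave higher miR-147-3p (3.01 ± 0.57, limma adjusted p = 0.025), miR-223-3p (2.90 ± 0.59, 0.025) and miR-142a-3p (1.5 ± 0.34, 0.030). It gave lower miR-200a-3p (-2.26 ± 0.45, adjusted p = 0.025), miR-203-3p (-2.10 ± 0.48, 0.030), miR-205-5p (-1.67 ± 0.38, 0.030) and miR-31-5p (-1.33 ± 0.28, 0.025). In total 10 miRNAs were higher and 14 lower, 24 calls (41.7% up, or 65% up with miR-21a-5p and miR-1a-3p out of the totals). edgeR, the test planned for a count table, called 0 on the recovered reads, DESeq2 67 and limma without the trend 2. The count was 0 without UVB_180 replicate 2, UVB_180 replicate 3 or UVB_360 replicate 1, 1 without UVB_360 replicate 3, 15 without control replicate 2, 43 without control replicate 3 and 45 without UVB_90 replicate 3. None of the 20 named calls held without each of the 12 libraries.

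No miRNA was called between 180 and 90 mJ/cm2 by limma, edgeR or DESeq2, and 19 had an unadjusted limma p under 0.05. miR-21a-5p, miR-34c-5p and miR-200a-3p had log2 fold changes against control of 2.59, 2.56 and -2.12 at 180 mJ/cm2 and of 2.21, 2.24 and -2.19 at 90 mJ/cm2. The 95% interval of the difference between these doses reached 0.63 to either side at the median.

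Over all 4 groups, 237 miRNAs differed in limma's F test, and the linear term in dose passed for 177, 92 up and 85 down. Controls entered this fit as dose 0, so a similar change at every dose can also give such a slope. Departure from a straight line was not tested. The share of trends that were up was 52%, 40.8% with TMM factors and 70.3% with miR-21a-5p and miR-1a-3p out of the totals. The trends with the smallest p that rose were those of miR-147-3p (4.47 ± 0.58 log2 units over 360 mJ/cm2), miR-223-5p (3.42 ± 0.44) and miR-503-5p (2.35 ± 0.31), each with adjusted p = 0.00012. Those that fell were miR-200a-3p (-3.99 ± 0.53), miR-211-5p (-3.92 ± 0.53), miR-181d-5p (-2.59 ± 0.33) and let-7b-5p (-1.75 ± 0.21), again with adjusted p = 0.00012 each. miR-335-3p, which rose at each dose, had 166 ± 71.5, 150 ± 29.9 and 165 ± 64.2 CPM at 90, 180 and 360 mJ/cm2 against 24.5 ± 14.5 in controls. The F test called 154 without control replicate 1.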

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

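Tests of a smaller epidermal share, of a label swap, of a UVB_360 library carrying a UVB_90 label and of reads moving between siblings were chosen only after the result was seen, as was the leaving out of miR-21a-5p and miR-1a-3p. All patterns were found in the same data that tested them.

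The responses to the highest and the lower doses differed for several miRNAs, by limma's test of the difference itself. For 360 minus 90 mJ/cm2, miR-147-3p (log2 difference 3.19, adjusted p = 0.0092), miR-223-3p (2.92, 0.011), miR-223-5p (1.81, 0.011), miR-142a-3p (1.78, 0.011), miR-139-5p (1.98, 0.015) and miR-21a-5p (0.82, 0.043) were higher. Lower were miR-200a-3p (-2.18, adjusted p = 0.011), miR-203-3p (-1.83, 0.027), miR-429-3p (-1.78, 0.026), miR-200b-3p (-1.5, 0.048) and miR-205-5p (-1.49, 0.026), with miR-211-5p (-2.83, 0.011), miR-181d-5p (-1.73, 0.011) and miR-31-5p (-0.96, 0.037). For 360 minus 180 mJ/cm2, miR-147-3p (3.01, adjusted p = 0.025), miR-223-3p (2.90, 0.025), miR-139-5p (1.86, 0.034), miR-223-5p (1.61, 0.030) and miR-142a-3p (1.5, 0.030) were higher. miR-200a-3p (-2.26, adjusted p = 0.025), miR-203-3p (-2.10, 0.030), miR-200b-3p (-1.80, 0.041), miR-429-3p (-1.68, 0.049), miR-205-5p (-1.67, 0.030), miR-181d-5p (-1.37, 0.040) and miR-31-5p (-1.33, 0.025) were lower. miR-31-5p stands apart because it rose at 180 mJ/cm2 (1.18) and was at -0.15 at 360 mJ/cm2. These miRNAs are the ones that the naming rule gives for dose against dose, with those always named, a scope set after the values were seen; among all named miRNAs, 38 differed for 360 minus 90 and 20 for 360 minus 180. None of these held without each of the 12 libraries: all 14 named here for 360 minus 90 mJ/cm2 were lost without UVB_90 replicate 1 or 2, where the count of calls was 0, and all 12 for 360 minus 180 mJ/cm2 without UVB_180 replicate 2 or 3, where it was also 0.

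Of the 3 doses, the epithelial list had its lowest median at 360 mJ/cm2 (-1.90, camera adjusted p = 1.9e-05, and adjusted p = 0.50 with an estimated correlation). Taken as the whole cause, a smaller share of epidermal cells would lower miR-200a-3p and miR-200b-3p, from a shared transcript, alike. Their log2 ratio changed by -2.30 ± 0.22 from control, that of miR-429-3p to miR-200b-3p by -1.43 ± 0.30 and that of miR-141-3p to miR-200c-3p by -1.79 ± 0.32. This argues against a smaller share as the whole cause of the difference from control. At 180 mJ/cm2 the ratios had already changed, by -1.84 ± 0.22, -1.55 ± 0.30 and -1.68 ± 0.32 in the same order. They therefore cannot decide whether a smaller share accounts for the further fall from 180 to 360 mJ/cm2. Reads taken up by miR-21a-5p and miR-1a-3p are argued against too, since without both the median was -1.66 (quartiles -2.17 and -1.12). A partial loss of epidermis together with a change of miRNA processing or stability under UVB may remain, which no test here separates.

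UVB_90 replicate 3 lay nearer to the UVB_360 libraries than the other UVB_90 libraries did, with higher myeloid and lower epithelial miRNAs. A swap of labels with a UVB_360 library is argued against, because 0 of the 3 UVB_360 libraries correlated better with UVB_90 replicate 1 or 2 than with a UVB_360 library. A UVB_360 library that carries a UVB_90 label stays open. On a score over 24 miRNAs, 0 at the UVB_180 mean and 1 at the UVB_360 mean, the library was at 0.56, against 0.73 to 1.18 for UVB_360 and -0.29 and -0.27 for UVB_90 replicates 1 and 2, and the 3 UVB_360 scores span more than the gap. UVB_180 replicate 1 was at 0.23, and a stronger local response or uneven exposure may also account for such libraries, which was not tested.

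Within the miR-200 family at 90 mJ/cm2, miR-200a-3p, miR-141-3p and miR-429-3p fell while miR-200b-3p (-0.59 ± 0.46) and miR-200c-3p (-0.63 ± 0.34) did not pass; without control replicate 1 or UVB_90 replicate 3 miR-429-3p no longer passed either (adjusted p up to 0.054). The ratios themselves changed, by -1.61 ± 0.22 for miR-200a-3p to miR-200b-3p, -1.15 ± 0.30 for miR-429-3p to miR-200b-3p and -1.22 ± 0.32 for miR-141-3p to miR-200c-3p. A general loss of GC-poor miRNAs in the extraction is argued against by Spearman's rho of -0.03 between the GC content of the hairpin side and fold change. This covered 512 of the 590 miRNAs (permutation p = 0.43, adjusted p = 0.52). Such a loss is also argued against by miR-200b-3p, whose hairpin side is the poorest in GC of the 5 (45.7%). The GC content of the mature arms was not tested, so a loss of particular GC-poor arms stays open. Against reads moving between siblings, 0 of the 5 had a positive log2 fold change, and the log2 of their summed CPM was 12.52 ± 0.91 (SD) at 90 mJ/cm2 against 13.52 ± 0.26 in controls, with 11.46 in UVB_90 replicate 3 and 13.02 and 13.07 in the others. It is left open because 3 of the 5 lay below 0 by more than 2 SE, a bound that replaced the sign alone after the values were seen, and miR-200b-3p was at -0.03 ± 0.41 without UVB_90 replicate 3. A difference in processing or stability was tested only through arm ratios. At 90 mJ/cm2 the 5p to 3p ratio rose for miR-200a (1.44, limma adjusted p = 0.0043) and miR-141 (0.89, 0.021). It did not pass for miR-200b (-0.47, 0.40) or miR-200c (0.33, 0.41), whose scarcer arm averaged 0.773 CPM. These ratios do not tell processing from stability.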

How the results depend on the processing

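edgeR and DESeq2 on recovered reads, TMM factors, both abundant miRNAs left out, identical arms merged and both libraries left out were tests chosen only after the result was seen. Of these, edgeR had been planned for a count table, and only its use on the recovered reads was chosen then. The counts at 360 mJ/cm2 against control stayed within 1.5 times under every alternative run (169 to 280), as did the trend (130 to 222). No direction of a call was reversed among the results of named miRNAs that could be followed under RLE or TMM factors, the replicate block, each library left out or both abundant miRNAs left out (which are then not tested themselves), or among the list tests that each setting run for them allowed. Scaling by the total alone is the reported fit, since the values are CPM. With each library left out, counts ranged from 50 to 175 at 90 mJ/cm2 (50 and 96 without control replicates 1 and 2, 84 without UVB_90 replicate 3), 90 to 196 at 180 mJ/cm2 (90 without control replicate 1, 106 without UVB_180 replicate 3), 183 to 252 at 360 mJ/cm2 and 0 to 0 for 180 against 90. They ranged from 0 to 88 for 360 against 90 (0 without UVB_90 replicate 1 or 2, 18 and 1 without UVB_360 replicates 1 and 3) and 0 to 45 for 360 against 180 (0 without UVB_180 replicate 2 or 3 or UVB_360 replicate 1, 1 without UVB_360 replicate 3, 15 and 43 without control replicates 2 and 3, 45 without UVB_90 replicate 3). They ranged from 154 to 247 for any difference (154 without control replicate 1), 130 to 192 for the trend and 12 to 26 for lists (12 without control replicate 3). Of the named calls, 23 of 50 at 90 mJ/cm2, 41 of 66 at 180 mJ/cm2 and 65 of 77 at 360 mJ/cm2 held without each library in turn. Where a group was left with fewer libraries, the fit assumes that they vary like the others.

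For 360 against 180 mJ/cm2 (24 calls), the count was 2 without limma's trend, 38 with a pseudocount of 10, 63 at an adjusted p of 0.10, 63 with only the groups compared, 116 at an unadjusted p of 0.05 with a fold of 1.5, 49 with both libraries left out, 0 with edgeR and 67 with DESeq2. For 360 against 90 mJ/cm2 (66), it was 43 without a filter and 144 at the unadjusted p, which for 180 against 90 mJ/cm2 gave 16 where the adjusted test gave 0. At 90 mJ/cm2 against control (151), it was 83 with only the groups compared and 71 with both libraries left out, both with fewer samples. Of the 63 tests of a list at a dose, 23 passed with camera, 13 with a mean of at least 10 CPM, 0 with an estimated correlation and 29 with fry, where 5 of camera's calls did not pass and 11 others did. The 5 were the epithelial list at 90 and 180 mJ/cm2 (fry adjusted p = 0.11 and 0.21) and Dlk1-Dio3 at each dose (0.18, 0.13 and 0.091). The 11 were p53-responsive and endothelial (0.031, 0.0047 and 0.0013) at each dose, hypoxia and miR-30 at 180, pigment cell at 90, and wound and miR-15/16 at 360 mJ/cm2. Unless stated, the cause was not tested.

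edgeR, on 497 miRNAs, called 171, 198 and 239 for the 3 doses against control, of which 146, 170 and 220 were limma's, and DESeq2 called 177, 195 and 248. TMM factors moved the median of all miRNAs by -0.13 at 180 mJ/cm2 and -0.10 at 360 mJ/cm2 relative to the total, and leaving both abundant miRNAs out moved it by 0.20 at 360 mJ/cm2, 0.15 for 360 against 90 and 0.13 for 360 against 180. Changes are to be read relative to these shifts, and small ones such as the Dlk1-Dio3 median of 0.30 lie close to them. No clear pairing by replicate number was seen, as 6 of 18 pairs of same-numbered libraries had correlated deviations over 0.1 (-0.22 to 0.24) and 3 libraries matched best with their own number. With 3 libraries per group, these values cannot exclude such a pairing. With the replicate block the counts were 155, 171 and 229 against control, 0, 68 and 30 between doses and 21 lists. Depth limits scarce miRNAs, since 3 reads were worth up to 0.948 CPM.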

Other observations

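Neither of the hypotheses on neighbouring hairpins and on arm ratios was tested only after its result was seen, nor were the splits of samples. The tests without identical or near-identical arms and with 1 arm per hairpin were chosen only after the result was seen, and the clusters and hairpins named were picked after their values were seen.

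At 360 mJ/cm2, log2 fold changes of miRNAs from neighbouring hairpins were on average more alike than those of randomly assigned miRNAs. Some clusters were mixed. In that from miR-379 to miR-3072, 55 arms ranged from -1.04 to 1.36, with 13 up and 4 down, and the arms of miR-143 and miR-145a ranged from -1.26 to 0.53. In other clusters the arms moved alike. In the X-linked cluster of miR-322, miR-503, miR-351, miR-450b and miR-542, which has been linked to muscle differentiation and cell-cycle arrest, 9 of 10 arms rose (median 1.38), with miR-503-5p going from 9.69 ± 2.94 to 58.7 ± 6.72 CPM and miR-322-5p from 35.2 ± 4.24 to 107 ± 9.5 CPM (mean ± SD, n = 3). All 4 arms of miR-132 and miR-212 rose (median 1.86), and all 4 of miR-34b and miR-34c (median 2.66). All 3 arms of miR-181c and miR-181d fell (median -2.69), with miR-181d-5p going from 906 ± 25.6 to 142 ± 31.4 CPM. In the cluster of miR-297, miR-466, miR-467 and miR-669 arms 15 of 27 arms rose, a count that is uncertain because near-identical arms share reads. The hypothesis that miRNAs of a genomic cluster change together was tested over 35 clusters with 234 miRNAs. The SD of log2 fold changes within clusters was 0.65, against a median of 1.09 and a lowest value of 0.95 in random assignments (permutation p = 1e-04, the smallest that the permutations drawn can give). Changes in shared transcripts may account for this, but the cause was not tested. Identical arms have no spread by construction. With 1 of each identical set kept the SD was 0.65 (lowest random value 0.93), without miR-297, miR-466, miR-467 and miR-669 arms 0.64 (0.95), and with 1 arm per hairpin besides, over 13 clusters, 0.59 (0.80).

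The arms of some hairpins nonetheless changed apart. Of 166 hairpins with both arms tested, 39 (23.5%) had a 5p to 3p ratio that differed between 360 mJ/cm2 and control (limma adjusted p under 0.05), 22 toward 5p and 17 toward 3p, and 22 of 84 (26.2%) did where both arms averaged at least 10 CPM. The ratio rose for miR-200a (2.90 ± 0.27 log2 units), miR-141 (1.95 ± 0.24) and miR-136 (1.68 ± 0.25) and fell for miR-145a (-1.79 ± 0.26). This may point to UVB-dependent arm choice or stability; scarce arms near the floor are compressed by the pseudocount, which the count with both arms above 10 CPM reduces.

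Other splits of the 12 samples tested chance as the source of the counts. With random assignments to 4 groups, 1 of 100 splits gave as many miRNAs as the real 237, the real one itself, and the highest other gave 129. With random doses 1 of 100 gave as many as the real 177, and the highest other gave 55. Both shares are the smallest that 100 splits can give. They argue against chance for both counts only if the libraries are independent samples, which the labels do not say. Splits of 3 against 3 number 10, too few for a share under 0.05. The real and highest other counts were 151 and 0 at 90 mJ/cm2, 181 and 2 at 180 mJ/cm2, 235 and 0 at 360 mJ/cm2, 0 and 5 for 180 against 90, 66 and 11 for 360 against 90 and 24 and 0 for 360 against 180; 1 of 10 splits gave as many as the real one in each, except 180 against 90, where all 10 did.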
